A study of Homo sapiens with 12 samples.

How the data were processed

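The values analysed were FPKM as deposited, per the labels, in 1 table of 60558 genes for IMR32 (8 libraries) and 1 table of 15700 genes for SH-SY5Y (4 libraries), 15651 of the latter protein-coding. The tables held 0 columns of other samples. Per the submitters' processing notes, reads were aligned to hg38 with HISAT2 and counted with featureCounts of Subread, and Picard was used. Versions of these tools, the features counted and the use of strand are not given in the sources used here. Per the labels' protocols, SH-SY5Y RNA was depleted of ribosomal RNA and sequenced on a BGISEQ instrument, and RNA of both lines was isolated with a Promega kit. Doses, times and RNA selection for IMR32 are not given in the sources used here.

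The length in the FPKM was found to be the gene span. Multiplying back gave whole reads within 0.01 for 100% of IMR32 genes and for 95.8% to 96.0% of SH-SY5Y genes, using spans of GENCODE 29 for 15687 SH-SY5Y genes. Read totals came from this step and ran from 18.4 M (nutlin replicate 2) to 43.0 M (nontreated replicate 1). The SH-SY5Y totals cover more genes than the table does.

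Genes with a mean of at least 1 FPKM over the libraries of a table were tested on log2(FPKM + 1), 6298 in IMR32 and 5908 in SH-SY5Y. The gene span includes introns, so this filter also leaves out long genes with many reads. The lncRNA gene CASC15, for example, had 1156 to 3786 reads per IMR32 library and stayed under it. Limma-voom, which filters on reads, tested 16944 and 13643 genes. Tests used limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend), with p-values adjusted by Benjamini and Hochberg and a threshold of 0.05. The 8 IMR32 libraries shared 1 fit with 4 residual and 3.28 prior degrees of freedom. The SH-SY5Y fit had 2 residual degrees of freedom and an infinite prior. Gene lists, 27 in all, were tested with camera of limma at a preset correlation of 0.01 where at least 5 members were tested. Results were also read with an estimated correlation, and the self-contained test fry was run on the same lists. The version with an estimated correlation gave larger p-values even where that correlation lay under the preset one. For p53 targets in the knockdown it was −0.002, and the unadjusted camera p went from 2.67e-06 to 0.0303. A call lost with an estimated correlation therefore need not come from correlated genes. In the order nutlin, Selinexor, combination, combination against nutlin, combination against Selinexor, interaction and knockdown, fry kept 5 of 12, 12 of 12, 12 of 12, 11 of 12, 7 of 8, 4 of 11 and 0 of 7 list calls.

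Named genes followed a rule. NBAT1, MDM2, CDKN1A and XPO1 were named everywhere they were tested. Added to these were the 8 called genes with the largest change per direction (5 for the interaction and the comparisons of the combination with a single drug) whose groups did not overlap, and up to 4 members of each called list. Further list members are given with their values only. Some genes that met the rule are not reported here, and their places were not filled again. Of 156 named genes, 65 overlap another protein-coding or lncRNA gene and 59 overlap one on the opposite strand, CDKN1A and MDM2 among them.

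The comparisons, thresholds and most alternatives were chosen before the data were examined. These alternatives were a pseudocount of 0.1, no filter, a filter of 5 FPKM, median-of-ratios and quantile scaling, no trend, a robust fit, a log2 threshold of 1, a replicate block, each library left out, and a fit of only the 4 libraries compared. Chosen after seeing the data were limma-voom on recovered reads (mean of at least 10), a loess correction on transcript GC (span 0.5, 6285 genes), gene lists without Selinexor replicate 1, NBAT1 by limma-voom and gene lists under quantile normalization. So were gene lists over every member above 0 and over members with at least 1 FPKM in the reference group, which the change itself does not let in. Where 1 library is left, it is assumed to vary like the other groups.

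The method was tested on simulated data with 200 changed genes in 10 runs. For the combination fit, 73.2% of 1.5-fold and 99% of 2-fold changes were recovered, with 5% false calls. For the SH-SY5Y fit these were 80.8% and 100%, with 4% false calls. The simulated noise was normal, independent between genes and equal in all libraries, with each gene's fitted spread. These rates therefore do not cover a library that stands apart or deviations shared across genes, both of which the real data may hold. Replicate numbers were not treated as pairs, because deviations of equal number correlated at −0.4 to 0.39 in IMR32 and 0.15 in SH-SY5Y. The level of NBAT1 in SH-SY5Y was not analysed here.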

Results

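RNA was profiled by sequencing in a pair of human neuroblastoma cell lines. IMR32, a line with amplified MYCN, was left nontreated or was given nutlin, an inhibitor of the p53 ubiquitin ligase MDM2 that stabilises p53, or Selinexor, an inhibitor of the nuclear export receptor XPO1 (CRM1), or both drugs. No library is described as vehicle-treated in the labels, so each IMR32 fold against nontreated cells may include an effect of the vehicle. SH-SY5Y cells carried either a control short hairpin RNA or one against the long noncoding RNA NBAT1, and all of these cultures were treated with nutlin-3a at 10 µM for 24 h. The 12 libraries formed 6 groups of 2. Read totals in IMR32 were 43.0 and 42.6 M (nontreated), 36.8 and 18.4 M (nutlin), 42.5 and 36.2 M (Selinexor) and 41.8 and 42.2 M (both drugs). In SH-SY5Y they were 39.7 and 37.8 M (control hairpin) and 40.0 and 39.4 M (NBAT1 hairpin). Values are FPKM (reads per kilobase of gene span per 1e6 reads) as mean ± SD of 2 libraries. Each log2 fold change, and each fold made from it, is on the log2(FPKM + 1) scale. Such a fold is a ratio of FPKM + 1 and understates the ratio of the printed FPKM, most of all for genes of low FPKM. Folds of NBAT1 and CASC15 come from limma-voom on reads and are not on this scale. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical. No library pair looked like a single library deposited more than once.

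In IMR32, Selinexor replicate 1 stood apart from its partner. The correlation of log2 values across genes was 0.9844 for the Selinexor pair and 0.9961, 0.9961 and 0.9969 for the nontreated, nutlin and combination pairs. On the second principal component, which held 20% of the variance, that library lay at −16.6 and the other 7 between −1.29 and 5.82. The first component (62.4%) ordered the groups from nontreated (−15.72 and −14.64) through nutlin (−5.46 and −5.21) and Selinexor (4.32 and 3.7) to both drugs (16.13 and 16.88). Because all 8 libraries share 1 estimate of the spread, the counts of changed genes in every IMR32 comparison moved when either Selinexor library was left out.

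The first comparison addressed what nutlin alone did in IMR32. CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21 (chromosome 6, 36676460 to 36687339, hg38, ENSG00000124762), rose from 10.2 ± 0.17 to 71.6 ± 1.6 FPKM, a fold of 6.49 (log2 2.7, SE 0.07, adjusted p = 5.2e-06). MDM2, the p53 ubiquitin ligase that is itself a p53 target (chromosome 12, 68808177 to 68850686, ENSG00000135679), rose from 2.69 ± 0.027 to 6.05 ± 0.35 FPKM (adjusted p = 0.013). PHLDA3, an inhibitor of AKT signalling, rose 3.32-fold, the mitochondrial ferredoxin reductase FDXR 2.89-fold, the antiproliferative BTG2 2.71-fold and the BH3-only killer gene BBC3 (PUMA) 2.65-fold. Cell cycle genes were lower: the G1/S transcription factor E2F1 went from 17.5 ± 0.46 to 10.7 ± 0.41 FPKM (fold 0.634), the replicative helicase subunit MCM4 from 15.8 ± 0.16 to 10.2 ± 0.16 (fold 0.666) and the CDK1 inhibitory kinase PKMYT1 from 8.9 ± 0.28 to 4.81 ± 0.32 (fold 0.586). XPO1 (chromosome 2, 61477849 to 61538626, ENSG00000082898) was at 5.8 ± 0.34 against 6.48 ± 0.29 (adjusted p = 0.88).

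Of 6298 genes tested, 146 changed with nutlin, 78 higher and 68 lower, of which 17 and 1 by at least 2-fold. PLK2, a p53-induced polo-like kinase, rose 2.64-fold, RPS27L, a p53-induced relative of a ribosomal protein, 2.54-fold, and ARC, an immediate early gene of neurons, 2.49-fold. The largest fall, of the mitochondrial glutamine tRNA gene MT-TQ (log2 −2.49, adjusted p = 0.018), concerned a very short gene that rests on few reads. MYBL2, a cell cycle transcription factor (fold 0.635), the thymidine kinase TK1 (0.667), the cohesion factor CDCA5 (0.676) and the separase gene ESPL1 (0.679) were among the other genes that fell. The count of changed genes was 23 without nontreated replicate 1, 23 without nontreated replicate 2, 26 and 20 without nutlin replicates 1 and 2, 54 without either combination library, and 449 and 450 without Selinexor replicates 1 and 2. Of 32 named genes that passed, 10 passed without each library in turn (CDKN1A, PHLDA3, FDXR, BTG2, BBC3, PLK2, RPS27L, ARC, BAX and TNFRSF10B). MDM2 kept its size (log2 0.88 to 0.98) and lost its call without nontreated replicate 1 (adjusted p = 0.12), nontreated replicate 2 (0.11), nutlin replicate 1 (0.094) or nutlin replicate 2 (0.14), and also without a filter (0.93, adjusted p = 0.11).

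By gene list, the p53 response stood first with nutlin. Of 30 p53 targets tested, 24 rose, 0 fell and 6 did not pass (29 rose adjusted over the list alone, median log2 0.901, camera adjusted p = 1.81e-50). Among 10 pro-apoptotic p53 targets, 6 rose, 0 fell and 4 did not pass (8 adjusted over the list alone, adjusted p = 5.3e-15). The pore-forming BAX was at 32.5 ± 0.29 against 12.5 ± 0.28 FPKM, the death receptor TNFRSF10B up 2.14-fold and the stress protein TP53INP1 up 1.92-fold. DNA replication and G1/S genes fell in 17 of 27 with 0 higher and 10 not passed (24 adjusted over the list alone, median −0.456, adjusted p = 1.84e-33). Of 25 mitosis genes 5 fell, 0 rose and 20 did not pass (17 adjusted over the list alone, median −0.253, adjusted p = 3.89e-19). These included the proliferation antigen MKI67 (0.681) and the mitotic kinase AURKB (0.7). When Selinexor replicate 1 was left out, 15 fell. Homologous recombination and Fanconi anemia genes fell in 4 of 5, with 0 higher and 1 not passed (5 adjusted over the list alone, adjusted p = 3.25e-09). These included FANCI (0.736), RAD51AP1 (0.739), FANCG (0.74) and EME1 (0.744). These 5 lists also passed with an estimated correlation between genes (adjusted p = 0.00142, 0.0118, 0.0111, 0.0232 and 0.0183, in that order).

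The other nutlin lists that passed with the preset correlation moved by less and were lost with an estimated one. Cytosolic ribosomal protein genes, where family members share reads with near-identical copies, had a median of 0.233 (1 of 67 rose, 0 fell, 66 did not pass, 1 adjusted over the list alone, adjusted p = 8.24e-22, and adjusted p = 0.273 with an estimated correlation). RPS19 rose 1.49-fold, and 8 members rose without Selinexor replicate 1. Replication-dependent histone genes, also near-identical copies, had 2 of 15 higher, 0 lower and 13 not passed (6 adjusted over the list alone, adjusted p = 9.54e-05, and adjusted p = 0.273 with an estimated correlation). The 2 were HIST1H2AE (1.55-fold) and HIST2H2BE (1.53-fold), and 5 rose without Selinexor replicate 1. In the nuclear transport list 0 of 29 rose or fell, alone or over all genes (775 genes had an unadjusted limma p under 0.05), with a median of −0.074 (adjusted p = 0.00127, and adjusted p = 0.273 with an estimated correlation). RANBP1, a RAN-binding cofactor, was at −0.25 and the nuclear basket gene NUP153 at −0.19. Autophagy and lysosome genes had 2 of 14 higher, 0 lower and 12 not passed (2 adjusted over the list alone, adjusted p = 0.0259, and adjusted p = 0.4 with an estimated correlation). They were the protease CTSL (1.43-fold) and the sialidase NEU1 (1.24-fold). This call was lost without nontreated replicate 1 (0.0668) or nutlin replicate 1 (0.11), and 4 rose without Selinexor replicate 1. Adrenergic identity genes had 0 of 20 past the test (2 higher adjusted over the list alone, median 0.086, adjusted p = 0.0269, and adjusted p = 0.517 with an estimated correlation). GATA3 stood at 0.35 and CHGA at 0.37, and the call was lost under quantile normalization (0.107), without nontreated replicate 2 (0.152) and without nutlin replicate 1 (0.179).

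Nuclear genes of oxidative phosphorylation had 0 of 27 past the test and 0 adjusted over the list alone (median 0.086, adjusted p = 0.00716, and adjusted p = 0.382 with an estimated correlation). NDUFA4 stood at 0.28 and ATP5PB at 0.24, and the call was lost under quantile normalization (0.056) and without nontreated replicate 2 (0.152). The 13 mitochondrially encoded genes, 0 of which passed over all genes or over the list alone, had a median of −0.137 that quantile normalization set to 0 (adjusted p = 0.0202, and adjusted p = 0.498 with an estimated correlation). MT-ATP6 stood at −0.26, and the call was lost without nontreated replicate 2 (0.444), nutlin replicate 2 (0.475), Selinexor replicate 1 (0.0559) or Selinexor replicate 2 (0.0574). The remaining lists did not pass with nutlin. Apoptosis genes had 2 of 12 higher (BAX and BBC3), 0 lower and 10 not passed (3 higher and 2 lower adjusted over the list alone, adjusted p = 0.0631), which passed without nontreated replicate 1 (0.0205) or nutlin replicate 2 (0.0347). ATF4 stress response genes had 2 of 20 higher (the stress-induced SESN2, log2 0.5, and the mTORC1 inhibitor DDIT4, 0.7), 0 lower and 18 not passed (3 higher and 1 lower adjusted over the list alone, median −0.015 against a mean of 0.041, adjusted p = 0.969). Neuronal differentiation genes had 1 of 18 higher (the neurofilament NEFL, 0.45), 0 lower and 17 not passed (1 adjusted over the list alone, adjusted p = 0.0733). The unfolded protein response (17 tested, adjusted p = 0.755), heat shock (16, 0.501) and cholesterol synthesis (23, 0.794) had 0 members past the test, also adjusted over the list alone. The same held for ribosome biogenesis (32, 0.501, median 0.003 against a mean of −0.009), glycolysis and hypoxia (17, 0.755) and lncRNAs (7, 0.192). Mesenchymal genes had 0 of 6 past the test and 1 higher and 1 lower adjusted over the list alone (adjusted p = 0.364).

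**Figure D1:**
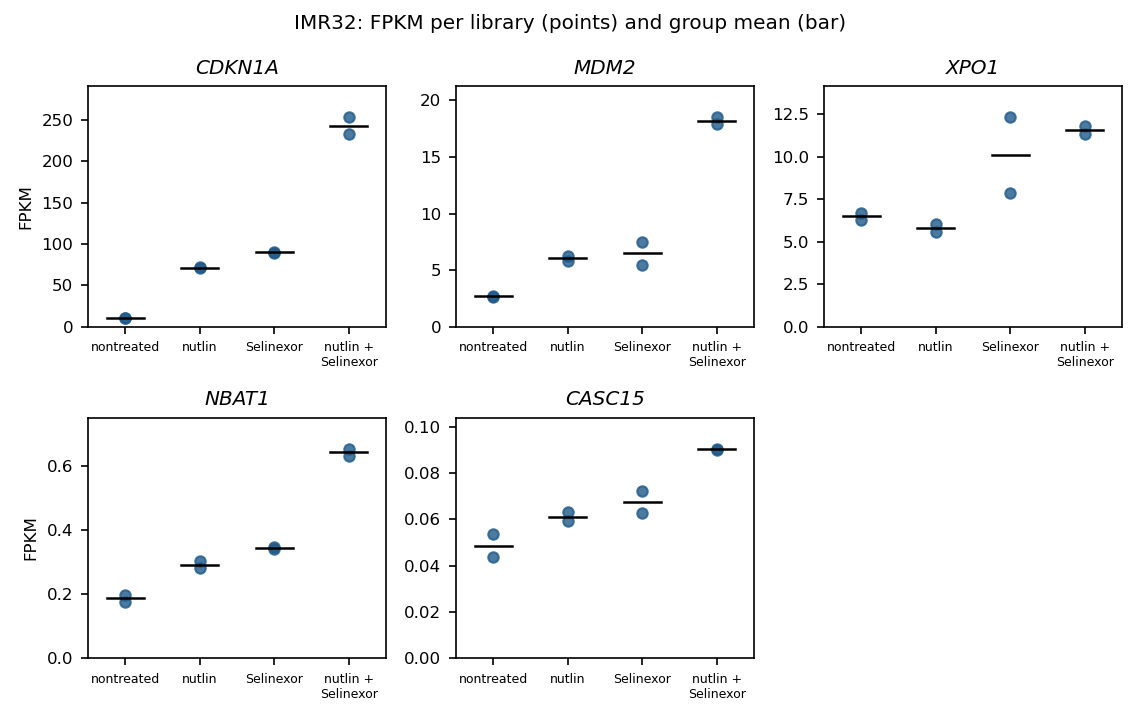
Expression in FPKM (vertical axes, linear) of CDKN1A, MDM2, XPO1, NBAT1 and CASC15 in the 4 IMR32 groups (horizontal axes), with 1 point per library and a bar at the mean of 2 libraries. CDKN1A stood at 10.2 in nontreated cells, 71.6 with nutlin, 90.1 with Selinexor and 243 with both.

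The next comparison addressed Selinexor alone in IMR32. CDKN1A rose 8.14-fold to 90.1 ± 1.1 FPKM (log2 3.02, SE 0.07, adjusted p = 2.3e-06) and MDM2 2.02-fold to 6.51 ± 1.4 (adjusted p = 0.0024). The arrestin-domain gene ARRDC3 rose 4.14-fold, the immediate early transcription factor EGR1 4.09-fold from 3.17 ± 0.39 to 16 ± 0.73 FPKM, PHLDA3 3.63-fold, FDXR 3.38-fold, ARC 3.23-fold, BBC3 3.11-fold and BTG2 3.1-fold. The interferon-induced gene IFI44 fell from 6.8 ± 0.38 to 2.62 ± 0.51 FPKM (fold 0.462, adjusted p = 0.00093), PKMYT1 to a fold of 0.504, MYBL2 to 0.509, MCM4 to 0.518 and the replication licensing factor CDC6 to 0.531. XPO1, the target of the drug, was at 10.1 ± 3.2 against 6.48 ± 0.29 FPKM (log2 0.54, adjusted p = 0.069), and this call depended on single libraries (0.83, adjusted p = 0.00091, without Selinexor replicate 1, and 0.24, adjusted p = 0.028, without Selinexor replicate 2). With all libraries XPO1 passed after GC correction (0.69, adjusted p = 0.001) and by limma-voom (0.6, adjusted p = 0.027).

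Selinexor changed 1052 of 6298 genes, 641 higher and 411 lower, of which 39 and 1 by at least 2-fold. The split depended on the scaling: 60.9% of the calls were higher with the deposited values, 42.7% after rescaling by median-of-ratios and 50% after quantile normalization. The deubiquitinase USP1 (0.537) and the serotonin receptor subunit HTR3A (0.543) were among the other genes with large falls. The count was 308 and 349 without nontreated replicates 1 and 2, 602 without either nutlin library, 572 and 573 without combination replicates 1 and 2, and 3054 without Selinexor replicate 2, with 1426 without Selinexor replicate 1. Of 51 named genes that passed, 34 passed without each library in turn.

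Of the 30 p53 targets, 25 rose with Selinexor, 0 fell and 5 did not pass (29 adjusted over the list alone, median 0.746, adjusted p = 3.31e-22). Pro-apoptotic p53 targets rose in 7 of 10 with 0 lower and 3 not passed (9 adjusted over the list alone, adjusted p = 5.63e-07). These included BAX (2.46-fold), TNFRSF10B (2.36-fold) and the death-domain gene PIDD1 (1.91-fold). In the DNA replication list 26 of 27 fell, 0 rose and 1 did not pass (27 adjusted over the list alone, median −0.647, adjusted p = 1.61e-23), with TK1 at a fold of 0.578. Mitosis genes fell in 23 of 25, with 0 higher and 2 not passed (23 adjusted over the list alone, adjusted p = 1.34e-14). These included MKI67 (0.571), the topoisomerase TOP2A (0.585) and cyclin A2 (CCNA2, 0.598). All 5 homologous recombination genes fell, with 0 higher and 0 not passed (5 adjusted over the list alone, adjusted p = 5.61e-06). The largest change was in XRCC3 (0.625). Cholesterol and lipid synthesis genes fell in 8 of 23, with 0 higher and 15 not passed (8 adjusted over the list alone, median −0.227, adjusted p = 5.75e-06). These included the isomerase IDI1 (0.693), the desaturase SCD (0.735) and TMEM97 (0.747). These 6 lists also passed with an estimated correlation (adjusted p = 0.00764, 0.0318, 0.0216, 0.0318, 0.0318 and 0.0318).

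Among lists that passed with the preset correlation and not with an estimated one, nuclear transport genes had 8 of 29 lower, 1 higher and 20 not passed with Selinexor (11 lower and 3 higher adjusted over the list alone, adjusted p = 1.26e-05, and adjusted p = 0.165 with an estimated correlation). The importin KPNA2 fell from 74.9 ± 3.3 to 47.4 ± 5.8 FPKM, its partner KPNB1 from 29.5 ± 0.36 to 20.3 ± 0.91, the importin recycling factor CSE1L to a fold of 0.686 and RANBP1 to 0.715. Adrenergic identity genes, the transcription factors and markers of the sympathetic neuroblast state, rose in 12 of 20, with 0 lower and 8 not passed (13 adjusted over the list alone, median 0.334, adjusted p = 4.65e-05, and adjusted p = 0.34 with an estimated correlation). These included TBX2 (1.72-fold), GATA3 (1.62-fold), HAND1 (1.46-fold), PHOX2A (1.44-fold) and MYCN (log2 0.53). Genes of the unfolded protein response fell in 8 of 17, with 0 higher and 9 not passed (11 lower and 2 higher adjusted over the list alone, adjusted p = 0.000132, and adjusted p = 0.165 with an estimated correlation). These included PDIA3 (0.685), CRELD2 (0.73), SDF2L1 (0.742) and the ER chaperone HSPA5 (0.783). Cytosolic ribosomal protein genes rose in 21 of 67, with 0 lower and 46 not passed (34 adjusted over the list alone, adjusted p = 9.05e-11, and adjusted p = 0.381 with an estimated correlation). Examples were RPS19 (1.53-fold), RPLP1 (1.4-fold) and RPS28 (1.39-fold). Histone genes rose in 6 of 15, with 1 lower and 8 not passed (10 higher and 1 lower adjusted over the list alone, adjusted p = 0.00128, and adjusted p = 0.342 with an estimated correlation). HIST1H4B rose 2.18-fold, HIST1H4E 1.67-fold and HIST1H2AE 1.59-fold, while HIST1H2BH fell to 0.653. Over the 9 histone genes with at least 1 FPKM in nontreated cells the list call was lost (0.116). The heat shock list had 2 of 16 lower, HSPA8 (0.768) and STIP1 (0.808), with 0 higher and 14 not passed (2 adjusted over the list alone, adjusted p = 0.00896, and adjusted p = 0.342 with an estimated correlation), and lost its call without Selinexor replicate 1 (0.0552).

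The other lists did not pass with Selinexor. The ATF4 list had 6 of 20 higher, 4 lower and 10 not passed (8 and 6 adjusted over the list alone, adjusted p = 0.545). SESN2 (log2 0.55), SLC3A2 (0.54), DDIT3 (0.51) and PPP1R15A (0.48) rose, and the aminoacyl-tRNA synthetases AARS (−0.26) and WARS (−0.23) and the serine synthesis gene PHGDH (−0.23) fell. The ribosome biogenesis list had 1 of 32 higher (ODC1, the polyamine synthesis enzyme, log2 1.11), 2 lower and 29 not passed (1 and 0 adjusted over the list alone, adjusted p = 0.281, with 3 higher without Selinexor replicate 1). Neuronal differentiation had 4 of 18 higher, 1 lower and 13 not passed (6 and 1 adjusted over the list alone, adjusted p = 0.334, with 3 lower without Selinexor replicate 1), and apoptosis 3 of 12 higher, 2 lower (CYCS and BIRC5) and 7 not passed (6 and 3 adjusted over the list alone, adjusted p = 0.345). Glycolysis and hypoxia had 1 of 17 higher, 2 lower and 14 not passed (2 and 4 adjusted over the list alone, median 0.042 against a mean of −0.014, adjusted p = 0.663). Mesenchymal identity had 1 of 6 higher (S100A6, log2 0.53), 0 lower and 5 not passed (1 adjusted over the list alone, median −0.019 against a mean of 0.075, adjusted p = 0.879). Oxidative phosphorylation had 1 of 27 higher, 0 lower and 26 not passed (0 adjusted over the list alone, adjusted p = 0.28, with a pass at 0.027 and 3 higher without Selinexor replicate 1). The mitochondrially encoded genes had 0 of 13 past the test, also adjusted over the list alone (adjusted p = 0.0596). That list passed without nontreated replicate 1 (0.000642), either nutlin library (0.039 each) or combination replicate 2 (0.0492), and quantile normalization set its median to 0 (0.96). Autophagy and lysosome genes had 2 of 14 higher (CTSL and NEU1), 0 lower and 12 not passed (2 adjusted over the list alone, adjusted p = 0.0707, with a pass at 0.0382 without Selinexor replicate 2), and the lncRNA list 3 of 7 higher, 0 lower and 4 not passed (4 higher and 1 lower adjusted over the list alone, adjusted p = 0.27).

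Both comparisons above used the same nontreated libraries. Nutlin and Selinexor shared 75 higher and 64 lower genes, against 7.9 and 4.4 for independent lists, and 0 genes moved in opposite directions. The correlation across genes of their fold changes was 0.638, against 0.5 in 100 simulations of unchanged groups with these controls, and the covariance was 0.0299 against a simulated 0.0054. The simulated overlap was 0. The 2 nontreated libraries were not split, since each part would hold 1, so part of the excess of shared calls over independent lists may come from the shared controls.

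Both drugs together gave the largest response in IMR32. CDKN1A reached 243 ± 14 FPKM, a fold of 21.8 over nontreated cells (log2 4.44, SE 0.07, adjusted p = 1.4e-07), and MDM2 18.2 ± 0.41 FPKM, a fold of 5.21 (log2 2.38, SE 0.12, adjusted p = 1.9e-05). EGR1 rose 9.67-fold to 39.3 ± 3 FPKM, ARC 6.88-fold, FDXR 6.2-fold, the immediate early gene IER3 6.11-fold, BTG2 5.83-fold and PHLDA3 5.79-fold. E2F1 fell from 17.5 ± 0.46 to 3.41 ± 0.1 FPKM (fold 0.239), PKMYT1 to 0.248, MCM4 to 0.249, MYBL2 to 0.277, CDC6 to 0.293 and TK1 to 0.314. XPO1 rose from 6.48 ± 0.29 to 11.6 ± 0.33 FPKM (fold 1.68, adjusted p = 0.015), a call lost without nontreated replicates 1 or 2 (0.063 and 0.078) or combination replicates 1 or 2 (0.064 and 0.081), or without a filter (0.072).

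The combination changed 1858 of 6298 genes, 986 higher and 872 lower (53.1% higher, or 35.2% after median-of-ratios rescaling), of which 119 and 64 by at least 2-fold. The U1 snRNA variant RNVU1-15 rose 6.48-fold and the small nucleolar RNA SNORD13 6.54-fold. Copies of small RNAs share reads, and MIR3193 (7.16-fold), MIR4746 (0.279) and MT-TQ (0.273) are very short genes with few reads, so these values are uncertain. The count was 949 without nontreated replicate 1, 1098 without nontreated replicate 2, 919 and 898 without combination replicates 1 and 2, and 3108 and 3106 without Selinexor replicates 1 and 2. Of 57 named genes that passed, 54 passed without each library in turn, the exceptions being XPO1, the ER oxidoreductase PDIA3 and MT-TQ.

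All 30 p53 targets tested rose with both drugs, with 0 lower and 0 not passed (30 adjusted over the list alone, median 1.399, adjusted p = 1.82e-25). Of 10 pro-apoptotic targets 8 rose, 0 fell and 2 did not pass (10 adjusted over the list alone, median 1.393, adjusted p = 1.29e-08). BBC3 rose 4.96-fold, TNFRSF10B 3.79-fold, BAX 3.41-fold and TP53INP1 3-fold. Every one of 27 DNA replication genes fell, with 0 higher and 0 not passed (27 adjusted over the list alone, median −1.2, adjusted p = 3.35e-24). All 25 mitosis genes fell too, with 0 higher and 0 not passed (25 adjusted over the list alone, median −0.687, adjusted p = 1.27e-16). These included MKI67 (0.401), CCNA2 (0.448) and AURKB (0.451). The 5 homologous recombination genes fell with 0 higher and 0 not passed (5 adjusted over the list alone, median −0.946, adjusted p = 5.53e-06). XRCC3 fell to 0.432, FANCG to 0.492, RAD51AP1 to 0.519 and FANCI to 0.525. These lists also passed with an estimated correlation (adjusted p = 0.00566, 0.0359, 0.0209, 0.0359 and 0.0359).

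Of 33 replication-dependent histone genes in the table, 15 passed the filter, which reads all 8 libraries and so lets in genes that are low in nontreated cells and high in the combination. Of these 15 histone genes, 12 rose with both drugs, 1 fell and 2 did not pass (12 higher and 1 lower adjusted over the list alone, median 1.293, adjusted p = 5.22e-08, and adjusted p = 0.158 with an estimated correlation). HIST1H2AE rose from 1.1 ± 0.057 to 7.32 ± 0.28 FPKM (3.96-fold), HIST1H4E 3.66-fold, HIST1H4B 3.58-fold and HIST1H2BG 3.52-fold. Over all 30 histone genes with a value above 0, 28 were higher and 2 lower (24 rose, 1 fell, median 0.891, adjusted p = 1.02e-15). Over the 9 with at least 1 FPKM in nontreated cells, 6 rose, 1 fell and 2 did not pass (median 1.193, adjusted p = 0.000676). Both choices of members were made after seeing the data. These histone transcripts normally carry no poly(A) tail, and their near-identical copies make single-gene values uncertain. Ribosomal protein genes rose in 55 of 67, with 0 lower and 12 not passed (65 adjusted over the list alone, median 0.418, adjusted p = 1.27e-16, and adjusted p = 0.284 with an estimated correlation). These included RPS19 (2.04-fold), RPS18 (1.57-fold), RPL34 (1.56-fold) and RPS27 (1.53-fold). In the lncRNA list 4 of 7 rose, 0 fell and 3 did not pass (4 adjusted over the list alone, adjusted p = 0.0354, and adjusted p = 0.284 with an estimated correlation). MALAT1, a nuclear-retained lncRNA, rose from 23.8 ± 1.4 to 76.8 ± 11 FPKM (3.12-fold), GAS5 1.71-fold, SNHG16 1.6-fold and MYCNOS 1.31-fold. That list call was lost without nontreated replicate 1 (0.0608) and stood at 0.05 without Selinexor replicate 1.

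Nuclear transport genes fell in 15 of 29 with both drugs, with 3 higher and 11 not passed (16 lower and 3 higher adjusted over the list alone, adjusted p = 0.000414, and adjusted p = 0.248 with an estimated correlation). RANBP1 fell to 0.579, KPNA2 to 0.608 and KPNB1 to 0.653, while XPO1, the exportin XPO6 (log2 0.26) and the mRNA export factor NXF1 (0.39) rose. Cholesterol and lipid genes fell in 8 of 23, with 0 higher and 15 not passed (8 lower and 1 higher adjusted over the list alone, adjusted p = 0.000694, and adjusted p = 0.0799 with an estimated correlation). FADS2 was at 0.675, TMEM97 at 0.686 and SCD at 0.694. Adrenergic genes rose in 10 of 20, with 1 lower (INSM1, log2 −0.35) and 9 not passed (13 higher and 2 lower adjusted over the list alone, adjusted p = 0.00126, and adjusted p = 0.389 with an estimated correlation). These included GATA3 and TBX2 (both 1.73-fold), SIX3 (1.56-fold) and CHGA (1.54-fold). Over all 31 adrenergic genes above 0 the list call was lost (0.315). The unfolded protein response list had 8 of 17 lower, 1 higher and 8 not passed (8 and 1 adjusted over the list alone, adjusted p = 0.00967, and adjusted p = 0.284 with an estimated correlation). SDF2L1 fell to 0.634, CRELD2 to 0.721, PDIA3 to 0.724 and PDIA4 to 0.745.

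Lists that did not pass with both drugs still held single genes that did. In the ATF4 list 7 of 20 rose, 5 fell and 8 did not pass (8 and 6 adjusted over the list alone, adjusted p = 0.349). SESN2 was at 0.94, DDIT4 at 0.86, PPP1R15A at 0.82 and DDIT3 at 0.77, against PHGDH at −0.49 and AARS at −0.41. Neuronal differentiation genes had 7 of 18 higher, 5 lower and 6 not passed (7 and 5 adjusted over the list alone, adjusted p = 0.274). The granin SCG2 was at 1.06, NEFL at 0.76 and STMN2 at 0.64. The apoptosis list had 3 of 12 higher (BBC3, BAX and PMAIP1), 2 lower (BIRC5 and HRK) and 7 not passed (4 and 3 adjusted over the list alone, adjusted p = 0.349). Glycolysis and hypoxia had 3 of 17 higher, 5 lower and 9 not passed (3 and 6 adjusted over the list alone, adjusted p = 0.349), with TPI1 at −0.59 and PGAM1 at −0.49. The ribosome biogenesis list had 4 of 32 higher, 4 lower and 24 not passed (2 and 3 adjusted over the list alone, median −0.053 against a mean of 0.004, adjusted p = 0.609), with ODC1 at 1.13. Heat shock had 3 of 16 lower, 0 higher and 13 not passed (3 adjusted over the list alone, adjusted p = 0.0522), and passed under quantile normalization (0.0378) and without nontreated replicate 2 (0.0173), Selinexor replicate 2 (0.0498) or combination replicate 2 (0.0494). Mesenchymal identity had 1 of 6 higher (S100A6), 0 lower and 5 not passed (1 higher and 1 lower adjusted over the list alone, adjusted p = 0.72). For oxidative phosphorylation 0 of 27 passed, also adjusted over the list alone (adjusted p = 0.349). The mitochondrially encoded list had 1 of 13 lower, 0 higher and 12 not passed (1 adjusted over the list alone, adjusted p = 0.131, with a pass at 0.00416 without nontreated replicate 1 and 0.0339 without combination replicate 2), and autophagy 2 of 14 higher (CTSL and NEU1), 0 lower and 12 not passed (2 adjusted over the list alone, adjusted p = 0.259). These counts moved without Selinexor replicate 1, to 7 higher and 1 lower for oxidative phosphorylation, 6 and 1 for autophagy, 6 and 4 for apoptosis, 1 and 7 for heat shock, and 6 and 7 for ribosome biogenesis.

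Set against nutlin alone, adding Selinexor raised CDKN1A 3.35-fold (71.6 ± 1.6 to 243 ± 14 FPKM, adjusted p = 4.3e-05) and MDM2 2.73-fold (6.05 ± 0.35 to 18.2 ± 0.41, adjusted p = 0.00049). EGR1 rose 4.45-fold, ARRDC3 4.37-fold, PLK2 2.18-fold and BTG2 2.15-fold, and among snRNA and snoRNA genes RNVU1-15 rose 5.55-fold and SNORD13 5.27-fold. MCM4 fell to 0.374, E2F1 to 0.377, CDC6 to 0.405, PKMYT1 to 0.423, MYBL2 to 0.436 and MCM5 to 0.445. MIR3193 (11.1-fold) and MIR499B (0.406) again rest on few reads. XPO1 rose 1.85-fold (adjusted p = 0.013, lost without nutlin replicates 1 or 2 at 0.09 and 0.066, or combination replicates 1 or 2 at 0.072 and 0.089, or without a filter at 0.066). In all 1022 genes changed, 521 higher and 501 lower (51% higher, or 32% after median-of-ratios rescaling), of which 58 and 15 by at least 2-fold. The count was 322 and 320 without nutlin replicates 1 and 2, 310 and 295 without combination replicates 1 and 2, and 2188 and 2187 without Selinexor replicates 1 and 2, and 34 of 54 named genes passed without each library in turn.

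Adding Selinexor to nutlin moved p53 targets further: 27 of 30 rose, 0 fell and 3 did not pass (30 adjusted over the list alone, adjusted p = 3.32e-21), and of the pro-apoptotic ones 8 of 10 rose, 0 fell and 2 did not pass (8 adjusted over the list alone, adjusted p = 8.57e-07). These included PIDD1 (2.03-fold), BBC3 (1.87-fold) and TP53I3 (1.6-fold). DNA replication genes fell in 26 of 27 with 0 higher and 1 not passed (27 adjusted over the list alone, adjusted p = 4.1e-24), and mitosis genes in 19 of 25 with 0 higher and 6 not passed (21 adjusted over the list alone, adjusted p = 2.69e-14). The 5 homologous recombination genes fell with 0 higher and 0 not passed (5 adjusted over the list alone, adjusted p = 1.86e-05), and cholesterol genes fell in 8 of 23 with 0 higher and 15 not passed (8 adjusted over the list alone, adjusted p = 3.92e-06). FADS2 was at 0.69, SCD at 0.703 and DHCR7 at 0.721, and 14 cholesterol genes fell without Selinexor replicate 1. These 6 passed with an estimated correlation (adjusted p = 0.00838, 0.0369, 0.0206, 0.0369, 0.0369 and 0.0369). Histone genes rose in 11 of 15 with 1 lower and 3 not passed (12 and 1 adjusted over the list alone, adjusted p = 2.5e-10, and adjusted p = 0.102 with an estimated correlation), for example HIST1H3B (3.3-fold). The lncRNA list had 4 of 7 higher, 0 lower and 3 not passed (4 adjusted over the list alone, adjusted p = 0.0143, and adjusted p = 0.25 with an estimated correlation), with MALAT1 up 2.56-fold.

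Adrenergic genes rose in 8 of 20 on adding Selinexor to nutlin, with 0 lower and 12 not passed (9 adjusted over the list alone, adjusted p = 0.00227, and adjusted p = 0.412 with an estimated correlation). TBX2 was at 1.45-fold, SIX3 at 1.44-fold and HAND2 at 1.35-fold. Over all members above 0 this call was lost (0.717). Ribosomal protein genes had 8 of 67 higher, 0 lower and 59 not passed (8 adjusted over the list alone, adjusted p = 8.58e-09, and adjusted p = 0.412 with an estimated correlation). RPS19 was at 1.37-fold and RPS27 at 1.3-fold, where quantile normalization turned RPS27 to −0.04. In this list 20 rose without Selinexor replicate 1. Nuclear transport genes had 5 of 29 lower, 3 higher and 21 not passed (5 and 3 adjusted over the list alone, adjusted p = 0.00257, and adjusted p = 0.263 with an estimated correlation). KPNA2 was at 0.639 and RANBP1 at 0.688, and 12 fell without Selinexor replicate 1. The unfolded protein response list had 6 of 17 lower, 1 higher and 10 not passed (9 and 1 adjusted over the list alone, adjusted p = 0.000728, and adjusted p = 0.218 with an estimated correlation). SDF2L1 was at 0.644 and HYOU1 at 0.747, with 11 lower without Selinexor replicate 1. The other 10 lists had adjusted p-values from 0.05 (heat shock) to 0.821 (ribosome biogenesis), the first of these just not past the threshold. Heat shock passed as lower without either nontreated library (0.0412 and 0.0411) or combination replicate 2 (0.0478).

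Set against Selinexor alone, adding nutlin raised CDKN1A 2.67-fold (adjusted p = 0.00024), MDM2 2.58-fold (adjusted p = 0.0017), IER3 2.74-fold, PLK2 2.16-fold and the stress gene GADD45A 1.91-fold (28.7 ± 2.4 to 55.6 ± 3.4 FPKM). RNVU1-15 rose 3.87-fold, SNORD3A (the U3 snoRNA) 2.67-fold and RNU6-9 3.11-fold, all with near-identical copies. E2F1 fell to 0.41, MCM4 to 0.481, PKMYT1 to 0.492, the licensing factor CDT1 to 0.502 and MCM5 to 0.532, and the short gene MT-TC to 0.443. XPO1 was at 11.6 ± 0.33 against 10.1 ± 3.2 FPKM (log2 0.21, adjusted p = 0.52, and −0.08 without Selinexor replicate 1). In all 291 genes changed, 133 higher and 158 lower, of which 29 and 4 by at least 2-fold. The count was 166 without either nontreated library, 162 without either nutlin library, 74 and 56 without combination replicates 1 and 2 and 2781 without Selinexor replicate 2, and 17 of 30 named genes passed without each library in turn.

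With nutlin added to Selinexor, p53 targets rose in 26 of 30 with 0 lower and 4 not passed (29 adjusted over the list alone, adjusted p = 2.17e-33, and adjusted p = 0.00329 with an estimated correlation). Pro-apoptotic targets rose in 7 of 10 with 0 lower and 3 not passed (9 adjusted over the list alone, adjusted p = 2.36e-10, and adjusted p = 0.0253 with an estimated correlation). TP53INP1 was at 1.82-fold and TNFRSF10B, PMAIP1 and BBC3 at 1.6-fold. Replication genes fell in 21 of 27 with 0 higher and 6 not passed (25 adjusted over the list alone, adjusted p = 3.68e-24, and adjusted p = 0.021 with an estimated correlation). Mitosis genes fell in 11 of 25 with 0 higher and 14 not passed (17 adjusted over the list alone, adjusted p = 3.19e-12, and adjusted p = 0.0506 with an estimated correlation). MYBL2 was at 0.543 and ESPL1 at 0.671, and 17 fell without Selinexor replicate 1. Homologous recombination genes fell in 4 of 5 with 0 higher and 1 not passed (5 adjusted over the list alone, adjusted p = 1.74e-05, and adjusted p = 0.0506 with an estimated correlation). The largest change was in FANCG (0.665). Histone genes rose in 11 of 15 with 0 lower and 4 not passed (12 adjusted over the list alone, adjusted p = 7.8e-17, and adjusted p = 0.0506 with an estimated correlation). HIST1H2BG and HIST1H2AE both rose 2.48-fold. Ribosomal protein genes had 0 of 67 past the test and 0 adjusted over the list alone (median 0.153, adjusted p = 2.05e-11, and adjusted p = 0.484 with an estimated correlation; 1181 genes in all had an unadjusted limma p under 0.05), and the lncRNA list 0 of 7 past the test with 4 higher adjusted over the list alone (adjusted p = 0.00243, and adjusted p = 0.181 with an estimated correlation), MALAT1 at log2 0.76. The other 14 lists had adjusted p-values from 0.188 (ATF4) to 0.994.

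The response to each drug was compared without and with the other, over 4 libraries against 4 others. Across 6298 genes, the Selinexor fold changes without and with nutlin correlated at r = 0.797 (rho 0.772), and those of nutlin without and with Selinexor at r = 0.62 (rho 0.533). Leaving out Selinexor replicate 2 gave 0.654 and 0.504. Genes are not independent replicates, so these values describe the libraries and carry no p. Among genes called in either comparison of a pair, 97.6% of 1393 and 95% of 319 had the same sign.

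The interaction of both drugs asks whether the combination departs from the sum of the single responses on the log2 scale. CDKN1A fell short of that sum by the largest amount among called genes (interaction −1.28, SE 0.1, adjusted p = 0.013): nutlin raised it by 2.7 alone and by 1.42 on top of Selinexor. PHLDA3 also fell short (−1.06, SE 0.12, adjusted p = 0.027). RNVU1-15 (1.73, adjusted p = 0.018), HIST1H2BG (1.07, adjusted p = 0.018), HIST1H4E (0.85, adjusted p = 0.021) and the immediate early transcription factor FOS (0.85, adjusted p = 0.018) exceeded the sum. A seventh gene, the lncRNA clone AC245014.3 (1.8, adjusted p = 0.016), lies outside the rule for named genes and is given after its values were seen. MDM2 was at 0.44 (SE 0.17, adjusted p = 0.94) and XPO1 at 0.35 (0.95). Of 6298 genes, 7 had an interaction, 5 positive and 2 negative. The split changed with the settings: a pseudocount of 0.1 left 1 call with 0 positive, a filter of 5 FPKM 3 calls with 0 positive, no filter gave 134 with 112 positive and GC correction 19 with 7 positive. Limma called 0 without nontreated replicate 1 or 2, nutlin replicate 1 or 2 or combination replicate 2, 2 without combination replicate 1, 15 without Selinexor replicate 1 and 91 without Selinexor replicate 2, against 315 genes with an unadjusted p under 0.05 in the full set and 8 calls, all negative, by limma-voom.

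Interactions of gene lists passed for 11 lists with the preset correlation and for none with an estimated one, and fry kept 4 of the 11. For p53 targets the estimated correlation was −0.024, under the preset one, so that loss cannot come from correlated genes. Histone genes were above the sum (2 of 15 higher, 0 lower, 13 not passed, 10 adjusted over the list alone, median 0.598, adjusted p = 2.63e-20, and adjusted p = 0.104 with an estimated correlation). The p53 targets were below it (2 of 30 lower, 0 higher, 28 not passed, 10 lower adjusted over the list alone, median −0.122, adjusted p = 1.43e-07, and adjusted p = 0.0649 with an estimated correlation, with the call lost at 0.059 without Selinexor replicate 2), as were pro-apoptotic targets (0 of 10 passed, 4 lower adjusted over the list alone, adjusted p = 0.018, and adjusted p = 0.386 with an estimated correlation). BAX was at −0.84 (adjusted p = 0.058), BBC3 at −0.73 and AEN at −0.45. DNA replication genes had a median of −0.084 (0 of 27 passed, 2 lower adjusted over the list alone, adjusted p = 0.011, and adjusted p = 0.4 with an estimated correlation), E2F1 at −0.63. Apoptosis genes had 0 of 12 past the test (2 lower adjusted over the list alone, adjusted p = 0.03, and adjusted p = 0.4 with an estimated correlation), BMF at −0.26. The remaining 6 lists had 0 members past the test over all genes or adjusted over the list alone. They follow with genes tested, adjusted p, and adjusted p with an estimated correlation. These were nuclear transport (29, 0.0212, 0.471), adrenergic (20, 0.03, 0.545) and oxidative phosphorylation (27, 0.0212, 0.5). The others were mitochondrially encoded (13, 0.03, 0.545), autophagy (14, 0.018, 0.471) and lncRNAs (7, 0.018, 0.4). Quantile normalization set the mitochondrially encoded median of 0.105 to 0. Leaving out Selinexor replicate 2 ended 8 of the 11 list calls, and leaving out Selinexor replicate 1 or nontreated replicate 2 ended 5 each. Without Selinexor replicate 1, 4 of 30 p53 targets were lower and 4 of 15 histone genes higher. Over all members above 0 the nuclear transport (0.51), mitochondrially encoded (0.54) and apoptosis (0.225) calls were lost. The other 11 lists had adjusted p-values from 0.0725 (ribosomal proteins) to 0.566 (mitosis), and the unfolded protein response was among them. The ribosomal protein list, with a median of −0.072, passed as lower without nontreated replicate 1 (2.19e-07), Selinexor replicate 1 (0.000882) or combination replicate 2 (0.00157). Its test turned upward without nontreated replicate 2 (0.248) or Selinexor replicate 2 (0.842). Ribosome biogenesis (0.138) passed as higher without nontreated replicate 2 (0.0492).

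NBAT1, the lncRNA targeted in the other cell line, could be followed in IMR32. It lies on chromosome 6 (22133205 to 22147193, minus strand, hg38, ENSG00000260455), antisense within the lncRNA gene CASC15 (21664185 to 22654455, ENSG00000272168). NBAT1 stood at 0.187 ± 0.015 FPKM in nontreated cells, 0.291 ± 0.016 with nutlin, 0.343 ± 0.0055 with Selinexor and 0.641 ± 0.015 with both drugs, from 78 to 385 reads per library. These levels are under the filter of 1 FPKM, so NBAT1 was tested by limma-voom on the recovered reads, a test chosen after its level was seen. NBAT1 was 3.43-fold higher with both drugs (log2 1.78, SE 0.14, adjusted p = 6.6e-06) and 1.84-fold higher with Selinexor (adjusted p = 0.0032), and with nutlin alone it was 1.55-fold its nontreated level (adjusted p = 0.086). CASC15 rose 1.87-fold with both drugs (adjusted p = 0.00018) and 1.39-fold with Selinexor (adjusted p = 0.019). Whether reads were counted by strand is not given in the sources used here, so reads of NBAT1 and CASC15 where they overlap cannot be told apart.

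In SH-SY5Y under nutlin, the NBAT1 hairpin was set against the control hairpin. NBAT1 was not analysed in these libraries, so its knockdown was not checked. With a single hairpin against it, other effects of that hairpin cannot be told from loss of NBAT1. Knockdown names this comparison. S100A10, an annexin partner (chromosome 1, 151982915 to 151993859, ENSG00000197747), fell from 21.1 ± 1.7 to 3.91 ± 0.62 FPKM (fold 0.222, log2 −2.17, SE 0.13, adjusted p = 1.5e-61). Its relative S100A6 fell from 150 ± 21 to 66.2 ± 2.6 FPKM (fold 0.446). SYT4, a synaptotagmin of neuronal vesicles (chromosome 18, 43267892 to 43277535, ENSG00000132872), rose from 13.8 ± 1.2 to 45.5 ± 1.1 FPKM (fold 3.14, adjusted p = 1.4e-28). The mitotic ubiquitin enzyme UBE2C rose 2.84-fold, the mitosis gene CDC20 2.59-fold, and MYC from 0.476 ± 0.056 to 2.16 ± 0.0069 FPKM. MDM2 fell from 34.3 ± 2.4 to 18.5 ± 1.6 FPKM (fold 0.552, adjusted p = 9.3e-08). CDKN1A was at 320 ± 30 against 418 ± 49 FPKM (log2 −0.38, adjusted p = 0.11), and XPO1 at 2.84 ± 0.53 against 2.67 ± 0.25 (log2 0.06, adjusted p = 0.79, with the sign turned to −0.01 without control replicate 1 and −0.08 without knockdown replicate 2). The CDKN1A value passed with limma-voom (adjusted p = 0.021), without the mean-variance trend (0.036), after quantile normalization (0.0044), after GC correction (0.032) and with the replicate block (0.014), and ranged from 0.0044 to 0.59 over all alternatives.

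With this hairpin 875 of 5908 genes changed, 471 higher and 404 lower, of which 10 and 8 by at least 2-fold. The receptor signalling inhibitor SPRY1 rose 2.59-fold, the angiogenesis inhibitor VASH1 2.49-fold, the kinetochore gene ZWINT 2.29-fold and the helicase RECQL4 2.07-fold. IGFBP3, an IGF-binding protein, fell to 0.388, TPRG1L to 0.467, the small heat shock gene HSPB7 to 0.47, FOXI3 to 0.474, the quinone reductase NQO1 to 0.48 and the peroxidasin gene PXDN to 0.49. In this fit the prior degrees of freedom were infinite, so every p-value rests on the variance expected at a gene's level, and very small ones should be read as ranks. The count was 1401 (919 higher) without control replicate 1, 551 (206 higher) without control replicate 2, 313 (162 higher) without knockdown replicate 1 and 238 (129 higher) without knockdown replicate 2, so the split between higher and lower genes depended on single controls. Of 39 named genes that passed, 22 passed without each library in turn, MDM2 among them (adjusted p up to 0.0062).

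With the knockdown 7 lists passed with the preset correlation, and none with an estimated one or by fry (smallest adjusted p = 0.0657). The estimated correlation was −0.002 for p53 targets and −0.036 for cholesterol genes, under the preset one, so correlated genes cannot explain these 2 losses. The filter reads all 4 libraries and lets in genes that are low in the controls and high in the knockdown, so 7 of 40 mitosis and 6 of 42 DNA replication genes were tested. All 7 mitosis genes tested rose, with 0 lower and 0 not passed (7 adjusted over the list alone, median 0.77, adjusted p = 6.33e-44, and adjusted p = 0.277 with an estimated correlation). These included TOP2A (2.02-fold) and cyclin B1 (CCNB1, 1.71-fold). Over all 40 mitosis genes, a choice made after seeing the data, 40 were higher and 0 lower (35 rose, median 0.335, adjusted p = 2.43e-30), while fewer than 5 reached 1 FPKM in the controls. In the DNA replication list 3 of 6 rose, 0 fell and 3 did not pass (3 adjusted over the list alone, adjusted p = 0.000933, and adjusted p = 0.404 with an estimated correlation), namely RRM2 (1.99-fold), MCM7 (1.41-fold) and MCM4 (1.18-fold). Over all 42 replication genes, 40 were higher and 2 lower (19 rose, median 0.15, adjusted p = 8.41e-18). Over the 5 with at least 1 FPKM in the controls the call was lost (0.294). Of 44 p53 targets 12 fell, 1 rose and 31 did not pass (12 lower and 1 higher adjusted over the list alone, median −0.205, adjusted p = 2.94e-05, and adjusted p = 0.333 with an estimated correlation). The ribonucleotide reductase subunit RRM2B fell to 0.66 and GADD45A to 0.698, while PLK2 rose 1.5-fold. Histone genes fell in 9 of 11, with 1 higher and 1 not passed (9 and 1 adjusted over the list alone, adjusted p = 3.04e-05, and adjusted p = 0.404 with an estimated correlation). These included HIST2H2BE (0.677), HIST1H2BK (0.703), HIST1H2AE (0.715) and HIST1H2AC (0.715). Ribosomal protein genes had 4 of 70 lower, 0 higher and 66 not passed (3 adjusted over the list alone, adjusted p = 8.99e-05, and adjusted p = 0.883 with an estimated correlation). RPS27 was at 0.685, RPS25 at 0.696, RPS4X at 0.717 and RPL23A at 0.731. Cholesterol and lipid genes rose in 6 of 21, with 1 lower and 14 not passed (7 and 1 adjusted over the list alone, adjusted p = 0.016, and adjusted p = 0.404 with an estimated correlation). Among these were FASN (1.66-fold), MVD (1.39-fold), HMGCS1 (1.3-fold) and DHCR7 (1.28-fold). The mitochondrially encoded genes had 2 of 13 higher, 0 lower and 11 not passed (11 higher adjusted over the list alone, median 0.4, adjusted p = 0.00178, and adjusted p = 0.883 with an estimated correlation). MT-ATP8 was at 1.85-fold and MT-CYB at 1.38-fold, where quantile normalization set the median and MT-CYB to 0 and lost the call (0.572). Since equal ranks get equal values there, this 0 can follow from the method and does not speak against a change. Mitochondrially encoded genes took 7.772% and 9.579% of reads in the knockdown libraries and 6.443% and 6.741% in the controls. Without control replicate 1 the replication (0.0551), cholesterol (0.069) and mitochondrially encoded (0.826) calls were lost, and without control replicate 2 the last of these (0.0774).

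The other knockdown lists did not pass, with adjusted p from 0.125 to 0.977. Neuronal differentiation genes had 4 of 17 higher, 6 lower and 7 not passed (4 and 7 adjusted over the list alone, adjusted p = 0.977). SYT4 and the growth cone gene GAP43 (log2 0.89) rose, and NEFL (−0.67), PRPH (−0.67), L1CAM (−0.6) and NEFH (−0.55) fell. Mesenchymal identity had 3 of 13 higher (LUM, COL1A1 and COL3A1), 2 lower (S100A6 and FN1) and 8 not passed (3 and 2 adjusted over the list alone, median 0.074 against a mean of −0.002, adjusted p = 0.977). Adrenergic identity had 3 of 24 higher, 3 lower and 18 not passed (3 and 3 adjusted over the list alone, median −0.007 against a mean of 0.012, adjusted p = 0.897), with CHGA at 0.72 and HAND1 at −0.7. Oxidative phosphorylation had 4 of 29 higher, 0 lower and 25 not passed (4 adjusted over the list alone, adjusted p = 0.462), and nuclear transport 2 of 28 higher, 1 lower and 25 not passed (2 and 1 adjusted over the list alone, adjusted p = 0.462). Pro-apoptotic p53 targets and apoptosis genes each had the same 2 of 10 lower (BAK1 and PMAIP1). Each list had 0 higher and 8 not passed (2 adjusted over the list alone, adjusted p = 0.462). Autophagy genes had 2 of 14 lower (SQSTM1 and MAP1LC3B), 0 higher and 12 not passed (2 adjusted over the list alone, adjusted p = 0.526), glycolysis 2 of 16 lower, 0 higher and 14 not passed (2 adjusted over the list alone, adjusted p = 0.529), heat shock 1 of 17 lower, 0 higher and 16 not passed (0 adjusted over the list alone, adjusted p = 0.461), and ribosome biogenesis 2 of 31 higher, 0 lower and 29 not passed (1 adjusted over the list alone, adjusted p = 0.125, with a pass at 0.00453 without control replicate 2). The unfolded protein response had 1 of 19 higher, 3 lower and 15 not passed (1 and 4 adjusted over the list alone, median 0.042 against a mean of −0.005, adjusted p = 0.853). For ATF4 genes 0 of 21 passed, also adjusted over the list alone (adjusted p = 0.853), interferon response genes had 1 of 9 higher (IFI6), 1 lower (TAP1) and 7 not passed (1 and 1 adjusted over the list alone, adjusted p = 0.853), and inflammatory NF-κB genes 1 of 8 higher (NFKB2), 0 lower and 7 not passed (1 adjusted over the list alone, median −0.064 against a mean of 0.005, adjusted p = 0.897).

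**Figure D2:**
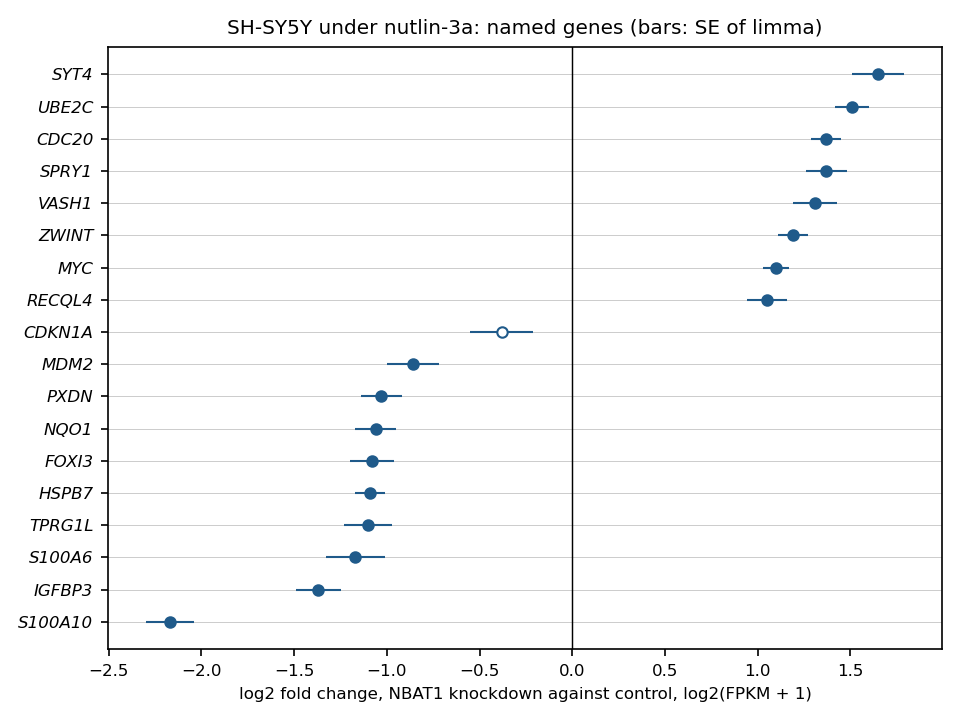
Log2 fold change of 18 named genes in nutlin-treated SH-SY5Y cells, NBAT1 hairpin against control hairpin, on the log2(FPKM + 1) scale (horizontal axis), with bars for the SE of limma from 2 libraries per group. An open circle marks CDKN1A (−0.38), which did not pass, and the range runs from S100A10 at −2.17 to SYT4 at 1.65.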

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

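Of the tests weighed here, those of read depth, S phase and the log scale were chosen after the result was seen, and so was the read sum used for non-polyadenylated RNAs.

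Selinexor replicate 1 differed from replicate 2, with an SD of the difference of 0.259 over genes against at most 0.13 in the other IMR32 pairs. A large part of it followed transcript GC (rho 0.84), and a loess on GC lowered the SD from 0.259 to 0.161. The ratio to the largest SD of the other pairs went from 1.99 to 1.26, just above the bound set beforehand. Whether a GC bias in 1 library explains all of the difference thus stays undecided. For a stronger drug response in replicate 1, the difference correlated at 0.005 with the Selinexor effect in 4 other libraries. That correlation was taken without GC correction, so it cannot exclude a response hidden under the GC difference. Lower depth was excluded, since replicate 1 had 1.17 times the reads of replicate 2.

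Histone genes (12 of 15 rose, median 1.29, or 0.891 over all 30 members above 0) and 13 of 18 snRNA genes were higher in the combination. The histone list lost its call with an estimated correlation (0.158), and snRNA genes were not tested as a class. More non-polyadenylated RNA in these libraries might explain this, but 0 of the RNAs named for the test passed the filter, and their reads summed to 16 in the combination against 0, 3 and 3 in the nontreated, nutlin and Selinexor groups, which leaves it undecided. The signal recognition particle RNA RN7SL1, looked at after the result was seen, rose from 4.45 to 22.1 FPKM (log2 2.08, adjusted p = 5.4e-05). More cells in S phase would raise DNA replication genes by the prediction written for it, and these fell (median −1.2, SD 0.4). Phases of the cell cycle were not measured, and each drug alone also lowered these genes, so this fall cannot exclude it.

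CDKN1A (−1.28) and PHLDA3 (−1.06) had a negative interaction, and the other 28 of 30 p53 targets did not pass. The list median was −0.122, and its call was lost with an estimated correlation (0.0649) and without Selinexor replicate 2 (0.059). The log scale may produce it, because 70.8% of targets with a negative value (17 of 24) exceeded the linear sum of the single-drug increments, between the bounds of 75 and 25 set for the test, so this is undecided. Selinexor replicate 1 was excluded as the cause for CDKN1A, which stood at −1.29 without it.

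Further interactions passed with all libraries, each in 4 against 4, and 0 of 6 named genes passed without each library in turn. RNVU1-15 was at 1.73, HIST1H2BG at 1.07, HIST1H4E at 0.85 and FOS at 0.85. The list calls were all lost with an estimated correlation, and apart from 2 histone genes no member of the lists given next passed. Positive list medians were 0.598 (histones), 0.139 (lncRNAs), 0.105 (mitochondrially encoded) and 0.017 (nuclear transport). Negative list medians were −0.147 (adrenergic), −0.133 (oxidative phosphorylation), −0.126 (autophagy), −0.085 (apoptosis), −0.084 (DNA replication) and −0.066 (pro-apoptotic p53 targets). Single libraries moved them: the mitochondrially encoded median was −0.007 without nontreated replicate 2 and −0.014 without nutlin replicate 2, that of nuclear transport 0 without nutlin replicate 1, and without Selinexor replicate 1 the adrenergic and autophagy medians were −0.047 and −0.035.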

How the results depend on the processing

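GC correction, limma-voom and the list and NBAT1 alternatives were chosen after the result was seen, all others before. Of 6295 alternatives for 333 named results, 5534 kept the result, 687 weakened it, 63 strengthened it and 11 reversed its sign, 2 of these among called genes. The counts of changed genes are given in the order nutlin, Selinexor, combination, combination against nutlin, combination against Selinexor, interaction and knockdown. The cause was not tested. The planned edgeR alternative was not run. Limma-voom on the reads recovered from the FPKM was run in its place.

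With a filter of 5 FPKM the counts were 70, 495, 786, 460, 143, 3 and 225, and the similarity of the Selinexor and nutlin responses 0.851 and 0.711. After GC correction the IMR32 counts were 501, 2200, 3025, 2144, 772 and 19. A log2 threshold of 1 gave 18, 40, 183, 73 and 33, and 18 for the knockdown. By limma-voom they were 362, 3160, 5830, 3251 and 905, and 2809 for the knockdown. Only the 4 libraries compared gave 351, 312, 2899, 2256 and 75. Without a filter the combination gave 4175, 2186 and 564 and the interaction 134, and a pseudocount of 0.1 left 1 interaction. Without a trend the knockdown count was 579. The replicate block gave 118, 1004, 1877, 968, 281, 9 and 1275, lost the interaction of the apoptosis list (0.0504) and changed no other list call.

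Leaving out 1 library gave ranges of 20 to 450, 308 to 3054, 898 to 3108, 295 to 2188, 56 to 2781, 0 to 91 and 238 to 1401, and similarities of 0.654 to 0.807 and 0.504 to 0.632, where a lone library is assumed to vary like the other groups. Signs turned for MT-ND6 with nutlin (0.04 without nontreated replicate 1 and 0.03 without nutlin replicate 1, range −0.44 to 0.04) and MT-ND5 with nutlin (0 by quantile normalization, 0.01 without nontreated replicate 2, range −0.3 to 0.01). By quantile normalization, RPS27 against nutlin was −0.04 and MT-CYB in the knockdown 0, a value that equal ranks of an abundant gene can give by construction. Without Selinexor replicate 1, XPO1 against Selinexor was −0.08 (range −0.08 to 0.51), the interaction of UQCRB −0.07 (range −0.07 to 0.47) and that of GAA 0.04 (range −0.37 to 0.04). XPO1 in the knockdown was −0.01 without control replicate 1 and −0.08 without knockdown replicate 2 (range −0.08 to 0.2).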

Other observations

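All comparisons in this part were chosen after the result was seen. With Selinexor and the combination, IFI44 fell by 1.11 and 1.16 on the log2 scale, while the NF-κB inhibitor NFKBIA rose by 0.38 and 0.41. the amplified driver of this line, MYCN, rose by 0.53 (adjusted p = 0.0093) and 0.46 (adjusted p = 0.0077). Its neighbour DDX1 was at −0.17 with Selinexor (adjusted p = 0.5), which rests on replicate 1. DDX1 stood at 163 and 238 FPKM in Selinexor replicates 1 and 2, against 232 and 212 in nontreated cells. In the knockdown, the cell adhesion gene NRCAM rose by 0.5 and the oxidative phosphorylation genes COX7C, NDUFV1 and CYC1 by 0.66, 0.45 and 0.44.

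On the linear scale, the combination level of p53 targets was set beside the sum of the single-drug increments and the product of the single-drug folds. CDKN1A stood at 243 FPKM, against a sum of 152 and a product of 633. MDM2, at 18.2, exceeded both its sum of 9.87 and its product of 14.6. FDXR (22.6, against 19.1 and 42.5), BTG2 (31, against 25.4 and 49.5) and BBC3 (8.48, against 8.12 and 22.2) lay between sum and product. PHLDA3 (36.7, against 37.8) and BAX (45, against 52.2) lay under their sums.

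Classes of noncoding genes were counted in the combination and not tested as classes, and the filter over all 8 libraries lets in small RNAs that are high in the combination alone. Of 457 lncRNA genes 153 were higher and 14 lower (median 0.22), of 18 snRNA genes 13 were higher and 0 lower (median 1.4), and of 8 snoRNA genes 5 were higher and 0 lower (median 0.52). Of 16 miRNA genes 2 were higher and 2 lower (median 0.05), of 16 mitochondrial tRNA genes 3 were higher and 3 lower (median 0.25), and of 5 miscellaneous RNA genes 3 were higher and 1 lower (median 0.51). Protein-coding genes were 743 higher and 841 lower of 5495.

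The NBAT1 knockdown in SH-SY5Y was set beside the drug responses in IMR32 over 4693 genes, in separate tables and different lines. The correlation was −0.25 (rho −0.266) with nutlin, −0.088 (rho −0.011) with Selinexor and −0.247 (rho −0.234) with the combination. The drug comparisons share the nontreated libraries, and the share of opposite signs over all these genes was not counted. Genes called in both had opposite signs in 19 of 22, 95 of 129 and 161 of 210 cases. UBE2C (−0.69 in the combination and 1.51 in the knockdown), CDC20 (−0.5 and 1.37), ZWINT (−1.17 and 1.19) and MDM2 (2.38 and −0.86) were among these.

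Lists with fewer than 5 tested genes were left untested. In IMR32 the highest members were NGFR (3.21 FPKM) among Schwann cell markers, CD14 (0.292) among immune and ESAM (0.0705) among epithelial and endothelial markers, B2M (16.2) among interferon genes and NFKBIA (11) among NF-κB genes. In SH-SY5Y they were FANCG (4.06), SOX9 (16.1), CD14 (0.378), ESAM (1.05) and MYCNOS (0.0838) for the recombination, Schwann cell, immune, epithelial and endothelial, and lncRNA lists.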
